A study of Mus musculus with 9 samples.

How the data were processed

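Epidermal RNA of 9 mice was sequenced, in libraries that the labels' protocols describe as column-purified RNA, poly(A) selection and a strand-specific kit. The labels do not say which strand setting was used for counting. The deposited table holds values per gene labelled as DESeq counts, a never-negative signal called normalized counts here. How the authors scaled it is not stated beyond that label. Its header names the mice, and the submitters' processing notes name STAR, DESeq2 and the builds GRCm38 and mm10, with no versions. Aligner settings, the counting tool and the annotation release are not given in the sources used here.

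The values are not whole numbers, and they are not whole multiples of a single step per library. Only 36.93% to 56.93% of the low values were whole multiples of the commonest lowest value, within a tolerance of 0.02, so whole reads could not be recovered and no count model was run. Column totals are therefore totals of normalized counts, and the read depths given are estimates. The table had 24972 rows, of which 26 with date-like names were left out (0.128% to 0.158% of each total). Of the 24946 genes kept, 4601 were at 0 in every library, and 24464 names were found in GENCODE M21. The table has no mitochondrial gene names, so that share could not be used to judge RNA quality.

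Groups and mouse numbers came from the sample titles. The numbers are not shared between groups, so they show no pairing, and shared litters or handling cannot be read from them. They have a gap between KO male 3 and KO male 5, for which no reason was found. No replicate pair held identical values, and each pair differed by more than counting noise (chi-square per gene 24.8 to 245). The tests, the 30 gene lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. The design allowed for either raw counts or normalized values, and the form for normalized values was used.

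Genes with a mean of at least 10 normalized counts over the 9 mice (14345) were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(value + 1). The comparison over both sexes used genotype and an additive sex term. Comparisons within a sex, the interaction and the comparison of WT sexes used 4 group means, with the spread shared by all mice because groups hold 2 or 3. P-values were adjusted by the Benjamini-Hochberg method within each comparison and called under 0.05. The gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The single-gene test of Acly was an exact permutation test. Flg, Trdc, Trac and Trbc2 are list members with no row of that name in the table used here.

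Named genes were the 10 largest rises and the 10 largest falls over both sexes, and the 5 each way in the other comparisons. They needed an adjusted p under 0.05, a mean of at least 50, a symbol that is no clone, predicted-gene or pseudogene identifier and, except for the interaction, KO and WT mice that did not overlap within a sex. Up to 4 members with the smallest p were named in each list. Near-identical copies (stefin A, Sprr2, Lce and Gsta genes) and overlapping genes are reported as uncertain.

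The procedure was tested on simulated data with 50 of the 14345 genes changed at each fold. Over both sexes it recovered 40% of 1.5-fold, 72% of 2-fold, 92% of 4-fold and 100% of 8-fold changes. For 4-fold changes it recovered 64% in males, 68% in females, 52% in the interaction and 72% between WT sexes. Far more genes were called over both sexes in the real data than were changed here, so these shares need not hold there. Alternatives covered rescaling by a trimmed mean of M values, no filter, a mean of at least 50, limma without the trend, pseudocounts of 0.5 and 10, other designs, and leaving out each mouse. Limma-voom on approximate reads, a fit without both KO males and a sum of C1qtnf5 with Mfrp were added after seeing the data. The predictions for the explanations weighed at the end were also written after the results were seen. The neutrophil test at first left out Cxcr2, and with all other list members, under the same rule, its label went from excluded to open. A median over those members was tried too and not kept, because it was picked with the values known. A test of scaling by a few abundant genes was dropped, as the rise of the lists fixed its outcome. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.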

Results

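Polyadenylated RNA of the epidermis was sequenced from 9 mice, in a design that deleted Acly throughout the body under a tamoxifen-inducible Cre driven by the ubiquitin C promoter. Acly encodes ATP citrate lyase, the enzyme that turns cytosolic citrate into acetyl-CoA for fatty acid and sterol synthesis. The labels give 2 WT males, 2 KO males, 2 WT females and 3 KO females, each a separate numbered mouse, and the numbers of the labels are kept here (KO male 3, for example). The column totals were 28907793 to 36575214 normalized counts, and division by the commonest worth of 1 read put the depth at about 29500000 to 38400000 reads per library. The 20 most abundant genes took 10.4% to 11.3% of the total in WT libraries and 12.6% to 16.6% in KO libraries. Gene positions are those of GENCODE M21 on GRCm38. Fold changes are on the log2(value + 1) scale, which understates the change of low genes.

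Acly (ENSMUSG00000020917.17, chromosome 11, 100476353 to 100528000, minus strand, protein-coding) was lower in every KO mouse than in every WT mouse. WT libraries held 12699 to 14849 normalized counts and KO libraries 4741 to 6332, so that the KO mean was 37.2% of the WT mean. The KO mean was 34.4% of WT in males and 39.8% in females. The log2 fold change was -1.43 (SE 0.1, adjusted p = 0.000138, limma with Benjamini-Hochberg adjustment), and the real grouping was the only 1 of 126 groupings with a difference as large (exact permutation test, two-sided, p = 0.00794). The labels do not say which exons were deleted, and counts over the whole gene include reads from exons that remained.

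**Figure D1:**
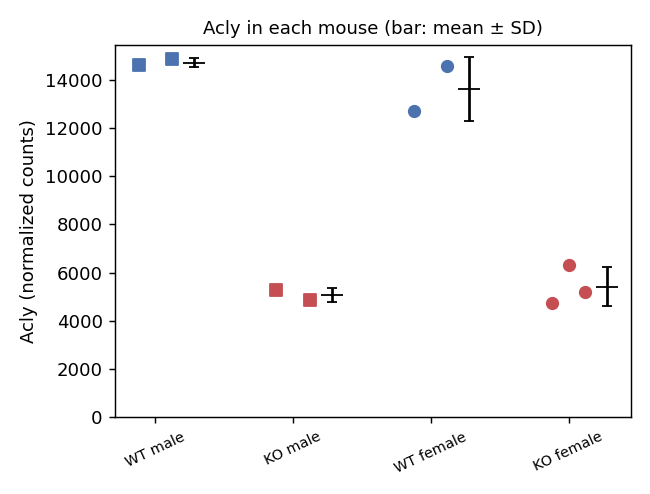
Acly in normalized counts (vertical axis) for each mouse of the 4 groups; points are mice (squares male, circles female) and the black mark beside them is the group mean ± SD. The KO mice sit between 4741 and 6332, below the WT mice at 12699 to 14849.

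The comparison of KO with WT epidermis over both sexes asks how epidermal RNA differed after deletion of Acly throughout the body. Effects of the loss within the epidermis and effects from other tissues cannot be told apart in this design. The largest rise that met the naming rule was that of Stfa3, a stefin A cysteine protease inhibitor, from 315 ± 131 (SD, n = 4) normalized counts in WT to 44600 ± 16900 (SD, n = 5) in KO, a log2 fold change of 7.08 (SE 0.38). S100a9, a subunit of calprotectin, rose from 33.1 ± 18.7 to 4250 ± 3170. The largest falls were in Hamp2, a hepcidin gene, from 454 ± 462 to 3.39 ± 5.93, and in Ifitm6, from 832 ± 379 to 14.4 ± 22.1. Neither was called in males alone (adjusted p = 0.0789 and 0.0581 in limma). Hamp2 fell by 9 on the log2 scale in females and by 4.2 in males, and WT females exceeded WT males by 3.55. Of 14345 genes tested, 2395 rose and 2410 fell in KO epidermis (limma, adjusted p under 0.05).

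The 10 largest rises that met the naming rule were Stfa3, S100a9, Tdh, Sprr2e, BC100530, BC117090, Sprr2b, S100a8, Olah and Spink7. Tdh, threonine dehydrogenase, rose from 23.5 ± 10.9 to 2900 ± 1190 (log2 fold change 6.88, SE 0.4, adjusted p = 6.49e-05 in limma). Olah, a thioesterase that releases medium-chain fatty acids, rose from 5.43 ± 4.86 to 449 ± 245 (6.36, SE 0.79). Spink7, a serine protease inhibitor, rose from 0.716 ± 1.43 to 211 ± 222. Stfa3, BC100530 and BC117090 are near-identical stefin A copies, and Sprr2b and Sprr2e belong to a family of close copies, so the share of each copy is uncertain. The 10 largest falls were Hamp2, Ifitm6, Npy1r, Rspo3, B4galnt2, Usp18, Iigp1, Chrnb4, Npr3 and Ces1d. Npy1r, a neuropeptide Y receptor, fell by 5.68 on the log2 scale (SE 1.02), and Rspo3, an amplifier of Wnt signalling, fell by 4.62 (SE 0.87). On the first principal component (57.8% of the variance) the WT mice scored -62.8 to -48.1, KO male 3 scored 1 and the other KO mice 43.5 to 79.2. Without WT male 1 the count was 3151 genes, and without both KO males, an alternative chosen after seeing the data, it was 2899.

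Genes of cholesterol synthesis rose together. Of 25 list members tested, 21 rose and none fell, 4 did not pass, and 21 rose when adjusted over the list alone. Ebp, a sterol isomerase, rose from 1440 ± 60.8 to 4290 ± 952 (log2 fold change 1.56, SE 0.14), Cyp51, lanosterol demethylase, rose by 1.55 (SE 0.17), Acat2, which makes acetoacetyl-CoA, by 1.54 and Dhcr7, the last reductase of the pathway, by 0.99. The list median was 1.03, and camera with the preset correlation gave adjusted p = 1.46e-11, against adjusted p = 0.416 with an estimated correlation. Epidermal barrier lipid genes followed, with 18 of 24 members up and 1 down (21 and 1 adjusted over the list alone). Cers3, a ceramide synthase for very long acyl chains, rose by 1.52 (SE 0.24), Pnpla1, which makes acylceramide, by 1.38 and Abca12, a lipid transporter of lamellar granules, by 1.17. For barrier lipids camera gave adjusted p = 2.8e-07, and adjusted p = 0.416 with an estimated correlation.

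Lists for fatty acid metabolism moved in both directions. In de novo fatty acid synthesis 6 of 17 members rose and 2 fell (6 and 2 adjusted over the list alone). Scd2, a fatty acid desaturase, rose from 5990 ± 1950 to 23900 ± 6680 (log2 fold change 2.07, SE 0.16), and Acss2, which makes acetyl-CoA from acetate, rose from 1300 ± 205 to 2380 ± 686 (0.87, SE 0.19). Acaca, acetyl-CoA carboxylase, rose by 0.64, and the elongase Elovl5 fell by 1.12. Among 14 genes of acetyl-CoA supply other than ACLY, 3 rose and 3 fell (5 and 4 adjusted over the list alone): Slc16a1, a monocarboxylate transporter, rose by 2 (SE 0.17), Bdh1, of ketone body metabolism, by 1.66 (SE 0.2), and Pdk4, an inhibitory kinase of pyruvate dehydrogenase, fell by 2.1 (SE 0.39). In fatty acid oxidation 1 of 18 rose and 5 fell (1 and 5 adjusted over the list alone), with Hmgcs2, the ketogenic synthase, down by 1.83 and Decr1 down by 1.24. In fatty acid uptake and triglyceride handling 5 of 18 rose and 2 fell (5 and 2 adjusted over the list alone), with Fabp5 from 9720 ± 1100 to 57400 ± 29100 and Fabp4 down by 2.03. The camera adjusted p was 0.307 for de novo synthesis, 0.513 for acetyl-CoA supply, 0.321 for oxidation and 0.273 for uptake. Within males camera called de novo synthesis (adjusted p = 0.00262) and uptake (0.0112) up, against adjusted p = 0.409 with an estimated correlation for both, and in females it gave 0.871 and 0.915.

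Keratinocyte differentiation and stress lists rose while most basal markers fell. Of 30 wound and stress genes tested, 29 rose and none fell (29 adjusted over the list alone), with a list median of 5.19. Many of these members are close copies (Sprr2, Lce3 and stefin A genes), so 29 is not a count of separate signals. Serpinb3a, a protease inhibitor, rose from 19.1 ± 1.58 to 1210 ± 491 (log2 fold change 5.79, SE 0.3), and Stfa1 rose by 5.97 and Sprr2a3 by 5.49, both with near-identical copies. In the cornified envelope list 22 of 28 rose and none fell (24 adjusted over the list alone), with Tgm3, a transglutaminase, up by 2.99, Casp14, a caspase of terminal differentiation, up by 2.98 and Krt1 up by 2.58. Lce1g rose by 4.66 (SE 0.6), with close copies in its family. Those Lce1 copies are also members of the cornified envelope list, so its count holds the same limit. Of 12 basal markers 9 fell and 1 rose (10 and 1 adjusted over the list alone). Krt15 fell from 171000 ± 15000 to 56100 ± 26700, and Col17a1, a hemidesmosome collagen, fell by 0.85, whereas Krt14 rose by 0.97. The camera adjusted p was 7.3e-16 for wound and stress, 3.78e-09 for cornified envelope and 0.00542 for basal markers, against adjusted p = 0.416, 0.416 and 0.504 with an estimated correlation.

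Cell cycle genes rose in 20 of 30 members and fell in none (20 adjusted over the list alone), with Plk1, a mitotic kinase, up by 1.76 (SE 0.17) and Mki67 from 2310 ± 676 to 5870 ± 1200. Cytokine genes rose in 10 of 19 members and fell in 1 (10 and 1 adjusted over the list alone). Il1f6 and Il1f8, interleukin-36 cytokines, rose by 3.77 (SE 0.45) and 2.96 (SE 0.3), and Ccl20, a chemokine, by 3.29. Targets of the transcription factor NRF2 rose in 10 of 18 and fell in 2 (11 and 3 adjusted over the list alone), with Nqo1, a quinone reductase, from 205 ± 12.4 to 555 ± 67.8. ATF4 and stress response genes rose in 12 of 20 and fell in 1 (13 and 1 adjusted over the list alone). The serine synthesis gene Phgdh rose by 0.85 and Asns, asparagine synthetase, by 1.22, whereas Atf3 fell from 36800 ± 9650 to 18700 ± 3070. Camera gave adjusted p = 5.56e-09 for cell cycle, 0.00262 for cytokines, 0.00124 for NRF2 targets and 0.00372 for the ATF4 list. With an estimated correlation these were adjusted p = 0.479, 0.416, 0.416 and 0.534.

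In the circadian list 8 of 15 fell and none rose (9 adjusted over the list alone), with Nr1d1, a repressor of the clock, down by 0.83 (SE 0.18) and Hlf, a clock output factor, down by 1.45. In the interferon list 4 of 24 fell and 1 rose (2 and 1 adjusted over the list alone): Usp18 fell from 473 ± 80.8 to 61.1 ± 73.2, and Mx1, an antiviral GTPase, rose by 2.09. The share of interferon genes that fell was near that over all genes tested, where 2410 of 14345 fell. In the hair follicle stem cell list 7 of 13 fell and 1 rose (8 and 1 adjusted over the list alone), with Lgr6, a stem cell receptor, down by 1.51 and Postn, an extracellular matrix gene, up by 1.75. Sebaceous markers fell in 5 of 15 and rose in 2 (5 and 2 adjusted over the list alone), with Mc5r, a melanocortin receptor, down by 2.62 and Elovl3 up by 1.5. LXR targets fell in 2 of 10 and rose in 1 (2 and 1 adjusted over the list alone), with Abca1, a sterol exporter, down by 0.66. Their share of falls was also near that over all genes. In the hair shaft list 1 of 15 rose and none fell (0 adjusted over the list alone). Camera gave adjusted p = 0.00372 for the clock, 0.0332 for interferon, 0.0168 for hair follicle stem cells, 0.609 for sebaceous markers, 0.418 for LXR targets and 0.98 for hair shaft. With an estimated correlation the clock, interferon and stem cell lists had adjusted p = 0.416, 0.676 and 0.534. Within females camera called the sebaceous list down (adjusted p = 0.0166, against 0.547 with an estimated correlation). Within males it gave 0.159, in the upward direction.

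Markers of some other cell types moved with genotype, and for others few or none passed. Fibroblast genes fell in 8 of 13 members and rose in none (10 adjusted over the list alone), with Col6a1 from 1200 ± 106 to 540 ± 212. Langerhans cell and macrophage genes fell in 9 of 14 (9 adjusted over the list alone), with Adgre1 down by 1.45 and the antigen presentation gene H2-Eb1 down by 0.86. Melanocyte genes fell in 4 of 6 (5 adjusted over the list alone), with Dct, a melanin synthesis gene, from 524 ± 209 to 212 ± 72.5. Adipocyte genes fell in 4 of 7 and rose in 1 (4 and 1 adjusted over the list alone), with Cfd from 50 ± 32.5 to 6.23 ± 9.27. Endothelial genes gave 1 rise and 1 fall of 7 (1 and 2 adjusted over the list alone), T cell genes 1 rise of 10 (1 adjusted over the list alone), red blood cell genes 1 fall of 2 (1 adjusted over the list alone), and muscle genes 0 of 11 and mast cell genes 0 of 2 (0 and 0 adjusted over the list alone). Of 12 neutrophil markers only S100a8, S100a9 and Cxcr2 reached the level for testing, and these 3 rose (3 adjusted over the list alone). The other 9 had KO means of at most 5.92 (Mpo), with Csf3r at 1.55 in WT and 1.51 in KO, so the camera call for this list rests on 3 genes. Uty was the only call of 5 sex-linked genes (0 adjusted over the list alone), being listed at 0 in WT females and at 2.17 to 2.33 in KO females. Camera gave adjusted p = 0.00126 for fibroblasts, 0.00153 for Langerhans cells and macrophages, 0.0213 for melanocytes and 0.00169 for neutrophils, against adjusted p = 0.534, 0.475, 0.504 and 0.416 with an estimated correlation. It gave 0.224 for adipocytes, 0.513 for endothelium, 0.321 for muscle, 0.331 for T cells, 0.98 for mast cells, 0.168 for red blood cells and 0.321 for sex-linked genes.

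Over the 30 lists camera with the preset correlation of 0.01 called 9 up and 7 down. Within males it called 11 up and 7 down and within females 9 up and 5 down, and 0 in either sex with an estimated correlation. With an estimated correlation over both sexes camera called 0, and 1 list, NRF2 targets, had an unadjusted p under 0.05 (0.024), while fry called 15. Other groupings of the mice called up to 19 lists.

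**Figure D2:**
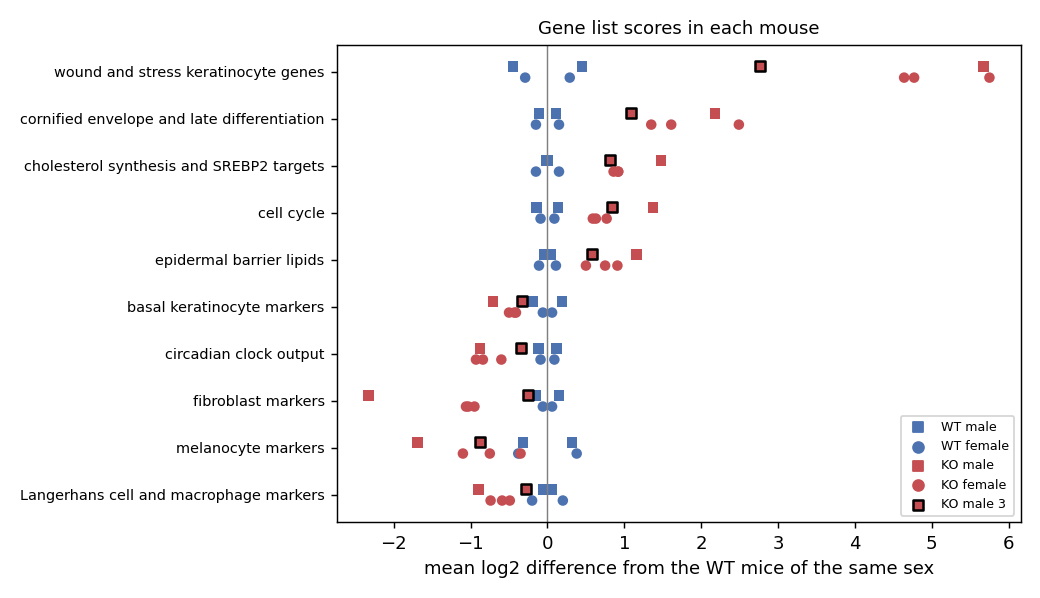
Mean log2 difference of each list's tested genes from the mean of the WT mice of the same sex (horizontal axis), for 10 lists; points are mice. KO male 3, outlined, scores 2.77 for wound and stress genes, where the other KO mice score 4.64 to 5.75.

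In males alone Cyp2g1, a cytochrome P450, had the largest rise, from 3.79 and 0 normalized counts in the WT males to 2742 and 1905 in the KO males (log2 fold change 10.03, SE 0.66, adjusted p = 0.00192). Tdh rose by 7.08 (SE 0.62), Stfa3 by 6.95 (SE 0.59), S100a9 by 6.58 (SE 0.93) and BC100530 by 6.42 (SE 0.88). B4galnt2, a glycosyltransferase, fell by 4.05 (SE 0.87), Col4a2, a basement membrane collagen, by 2.51, the glypican Gpc3 by 2.27 and Dnajc6 by 2.26. C1qtnf5 was listed at 0 in both KO males and at 198 and 65.1 in the WT males, and Acly fell by 1.54 (SE 0.16). The test called 460 genes in limma, 368 higher and 92 lower. Without WT male 1 it called 12, without WT male 2 it called 10, without KO male 3 it called 3786 (1859 higher and 1927 lower) and without KO male 5 it called 77 (71 and 6). Leaving out a female, which alters the shared spread, gave 240 without WT female 6, 243 without WT female 7, 83 without KO female 8, 145 without KO female 9 and 218 without KO female 10, and a fit of the 4 males alone called 0 with 2663 genes at an unadjusted p under 0.05.

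In females alone BC117090 rose by 7.76 (SE 0.75), Sprr2e by 7.72 (SE 1.23), Olah by 7.4 (SE 1), Stfa3 by 7.18 (SE 0.54) and S100a9 by 7.14 (SE 0.85). Hamp2 fell by 9 on the log2 scale (SE 1.07), Ifitm6 by 7.62, Npy1r by 6.31, the serpin gene Serpinb6e by 5.94 and Rspo3 by 5.36. Acly fell by 1.34 (SE 0.14). The test called 1389 genes, 774 higher and 615 lower, with a spread shared with the males. Without WT male 1 it called 832, without WT male 2 it called 808, without KO male 3 it called 2917 and without KO male 5 it called 2903. It called 160 without WT female 6, 228 without WT female 7, 161 without KO female 8, 338 without KO female 9 and 678 without KO female 10, and a fit of the 5 females alone called 2468.

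The responses of the sexes were correlated. Males and females share no mice, and their log2 fold changes had Pearson r = 0.822 and Spearman rho = 0.8 across the 14345 genes, which are not independent replicates. Both sexes called 300 genes higher, against 19.9 for independent lists, and 76 lower, against 3.94, and 0 genes were called in opposite directions. The tests of the sexes share an estimate of the spread, so a gene with a small spread is likelier to pass in both. The values for independent lists are therefore not the overlap to be had without a shared response. Of 1473 genes called in either sex, 1452 had the same sign in both.

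**Figure D3:**
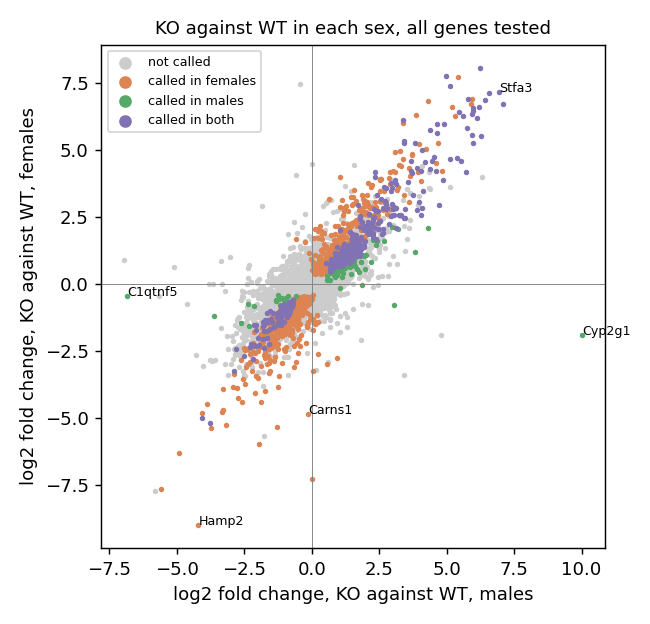
Log2 fold change of KO against WT in males (horizontal axis) and in females (vertical axis); each point is 1 of the 14345 genes tested, coloured by the sex in which it was called. Cyp2g1, Carns1 and C1qtnf5 lie away from the diagonal trend.

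A direct test of whether the response differed between the sexes called 3 genes. The KO effect on Cyp2g1 differed by -11.92 on the log2 scale, females minus males (SE 0.89, adjusted p = 0.00622 in limma). For Carns1, carnosine synthase, the difference was -4.71 (SE 0.42, adjusted p = 0.0139): WT females held 1552 and 2484 normalized counts, and the other 7 mice 51.2 to 82.9. For C1qtnf5 the difference was 6.39 (SE 0.68, adjusted p = 0.0348), and its reads overlap those of Mfrp. The unadjusted p was under 0.05 for 284 genes, where 717 would arise by chance. This test used the spread shared by all mice, and KO males 3 and 5 differed most among the replicate pairs (chi-square per gene 245). A number below chance is therefore no evidence that the sexes responded alike. Leaving out a mouse moved the number of genes called up as well as down. The count was 0 without WT female 7, with 502 genes at an unadjusted p under 0.05, and 1 without WT male 1, without KO male 5 or without KO female 10. Camera called 9 of the 30 lists for this difference, 4 up and 5 down, and with an estimated correlation it called 0, as did fry. The median was 1.38 in males and 0.92 in females for cell cycle genes, 0.47 and -0.67 for sebaceous markers, and 0.66 and -0.2 for de novo fatty acid synthesis. Camera gave adjusted p = 2.34e-10, 3.17e-10 and 1.75e-09 for these differences, against adjusted p = 0.571, 0.269 and 0.0658 with an estimated correlation. Between the WT sexes, the baselines of this test, cell cycle genes already had a median log2 fold change of 0.6 (females against males) and sebaceous markers of 0.55, with 0 genes called in either list over all genes and 12 and 2 higher in females adjusted over the list alone, so a difference at baseline and a different response to KO were not told apart. Limma-voom on approximate reads called 0 genes, with 293 at an unadjusted p under 0.05.

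**Figure D4:**
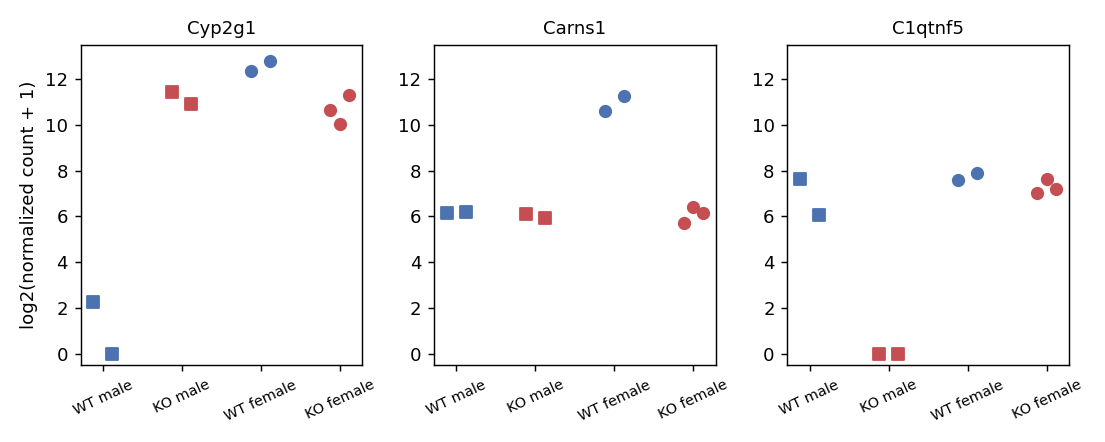
Cyp2g1, Carns1 and C1qtnf5 as log2(normalized count + 1) (vertical axis) in each mouse; points are mice (squares male, circles female). Cyp2g1 is low only in the WT males, Carns1 is high only in the WT females, and C1qtnf5 is listed at 0 in the KO males.

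Within WT mice, the comparison of females with males gave the baseline difference between the sexes. Xist, the RNA of the inactive X chromosome, was higher in females by 10.23 (SE 0.36), and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had log2 fold changes of -9.76, -10.52, -9.67 and -8.61. Cyp2g1 was higher in WT females by 11.43 (SE 0.66) and Carns1 by 4.78 (SE 0.31). The test called 8 genes in limma, 4 higher and 4 lower, and it called 14 without WT female 7. Camera called 5 lists higher in WT females and 6 lower, with adjusted p = 1.81e-18 for cell cycle and 0.000221 for sebaceous markers, against adjusted p = 0.619 and 0.706 with an estimated correlation, where 1 list, the sex-linked genes, was called (0.0298). Duxbl3, the remaining call (7.26, SE 0.73), falls outside the naming rule and is named here after its value was seen.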

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

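The interaction test, the gene counts and the list tests were set in advance. The tests of explanations below and the regroupings of the mice were run after the results they bear on had been seen, with predictions written afterwards.

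The KO effect differed between the sexes for 3 genes by the interaction test, with differences (females minus males) of -11.92 for Cyp2g1, -4.71 for Carns1 and 6.39 for C1qtnf5 on the log2(value + 1) scale. A wrong sex label is argued against by Ddx3y, at least 2849 in every male and at most 5.33 in every female, and by Xist, at most 24.7 in males and at least 15238 in females. For C1qtnf5, reads split with the overlapping Mfrp are a candidate explanation. After summing both genes the interaction had an adjusted p of 1, but only 3 genes passed this test, so not passing says little. The sums were 198 and 250 in the WT males and 118 and 191 in the KO males. In females they were 453 and 238 in WT and 315, 505 and 148 in KO. Mfrp was listed at 0 in WT male 1, WT female 7 and KO female 10, and C1qtnf5 in both KO males. For Cyp2g1 and Carns1 a biological effect of sex stays open and untested, since each rests on 2 WT mice.

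KO male 3 lay between the WT mice and the other KO mice on the first principal component. A wrong genotype label is argued against by Acly at 35.9% of the WT males. Admixed WT RNA is argued against too. On the linear scale 379 genes that fell in females stood in KO male 3 at a median 61.2% of the way from the WT males to KO male 5. That share would put Acly at 8684 normalized counts, and the upper quartile of 75% at 7322, against 5281 measured. The 495 rising genes stood at a median 34.3%, so rising and falling genes gave different shares. KO male 5 alone sets the KO end of this scale, and genes were kept only if it moved in the same direction. Lower depth is argued against by KO female 8, with about 30200000 estimated reads against 29500000 and a score of 48.3. A slower or smaller response of this mouse may account for its place, and no label allows a test.

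The wound, stress and cornified envelope lists rose in KO epidermis, with S100a8 and S100a9 among them. The camera call of both lists was lost with an estimated correlation (adjusted p = 0.416 for each). Fry called both, with adjusted p = 0.00198 for wound and stress and 0.00612 for cornified envelope. A larger share of keratinocytes would raise basal markers too, and their median was -0.51. Markers of fibroblasts, melanocytes, Langerhans cells and macrophages fell in most members and Krt14 rose by 0.97, so a larger share stays possible as a part of the change but not as its whole cause. Neutrophils stay open for S100a8 and S100a9, but on Cxcr2 alone. It reached a KO mean of 616 normalized counts, the highest of the 10 other list members. The remaining 9 had KO means below 10, with Csf3r at 1.51 (1.55 in WT), Ly6g at 0 and Retnlg at 0. A change of keratinocyte state may explain the rise, as a hypothesis found and tested on the same data.

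For the 4805 genes called over both sexes, 2 of 100 groupings of the mice into 5 and 4, the real one included, called as many. A random grouping therefore seldom called as many. The groupings were not balanced for sex, and they cannot speak to shared litters or handling. The highest other grouping called 5305 genes, more than the real one, and it placed KO male 3 with the 4 WT mice. That points to a structure of the samples in which KO male 3 stands apart from the other KO mice. For the 16 lists called by camera, 11 of 100 groupings called as many and the highest other called 19, so chance cannot be excluded for the number of lists.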

How the results depend on the processing

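Acly fell under every alternative run, with leave-one-out values of -1.5 to -1.39. Over both sexes, leaving out a mouse gave 3151 (without WT male 1) to 5573 genes (without KO male 3), and leaving out both KO males gave 2899. In males the range was 10 to 3786, with 306 genes without a filter, 179 without the trend, 243 with limma-voom and 0 with only the 4 males (2663 at an unadjusted p under 0.05). In females it was 160 to 2917, with 692 without the trend and 2468 with only the 5 females. The interaction gave 0 to 4 genes, and 0 with limma-voom. The WT sexes gave 6 to 14, and 13 with a pseudocount of 10. Camera called 15 to 16 lists without a mouse (interferon was lost without WT male 1, adjusted p = 0.224, and without KO male 5, 0.234), 18 without a filter, with adipocyte (adjusted p = 0.00757) and endothelial (0.0411) lists added, and 0 with an estimated correlation. Fry added acetyl-CoA supply (0.0324) and red blood cells (0.0194) and lost fibroblasts (0.0567), hair follicle stem cells (0.0824) and interferon (0.245). The fit without both KO males added sebaceous markers (0.0194) and lost hair follicle stem cells (0.0587), melanocytes (0.0911) and interferon (0.234). Where a mouse left out leaves a group with 1 mouse, that mouse is assumed to vary like the others. For a comparison within a sex, mice of the other sex enter only through the shared spread and the filter on level. The female count of 1389 therefore depends on the spread of the males. KO males 3 and 5 differed most among the replicate pairs (chi-square per gene 245, against 24.8 to 88.7 in the others). The cause of the other differences was not tested.

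Of 138 results called for the named genes, none reversed under any alternative run and 204 of 2548 values no longer passed. Most of these genes were picked for large effects without overlap of KO and WT mice, or for small p. Reversals were therefore unlikely from the start, and the other called genes were not followed in this way. Among the named genes and the lists, reversals occurred only in results that were not called. Xist over both sexes was -0.04 with a pseudocount of 10, -0.23 with limma-voom, -0.28 without both KO males, -0.27 without WT male 1, -0.05 without KO male 3 and 0 without KO male 5. Without a sex term Ddx3y was -0.53 and Eif2s3y -0.6, and without both KO males Kit was 0.14. The direction of camera reversed for hair shaft (adjusted p = 0.916 without a filter, 0.773 without both KO males, 0.536 without WT male 2, 0.798 without KO male 5, 0.69 without WT female 7, 0.819 without KO female 8), mast cell (0.481 without both KO males, 0.77 to 0.986 in 5 runs without a mouse), endothelial (0.91 without WT male 2) and de novo fatty acid synthesis lists (0.773 without both KO males). Over all runs without a mouse, reversed or not, Xist was -0.27 to 0.22, and the adjusted p was 0.394 to 0.983 for hair shaft and 0.368 to 0.91 for endothelial markers. The cause was not tested. In the simulation 1.5-fold changes were recovered in 40% of cases over both sexes, 8% in males, 6% in females and 0% in the interaction. The simulation did not vary the group sizes, and it changed far fewer genes than were called over both sexes here. Its shares therefore need not hold for these data.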

Other observations

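The family scan, and the use of the LXR list to weigh a cause, were chosen after the results were seen, whereas the LXR list and its camera test were set in advance. Gene families grouped by symbol root, with members of the fixed lists left out, gave 460 families of at least 5 tested genes. Kallikrein proteases rose in 7 of 8 members, with Klk13 from 19.8 to 788 normalized counts (log2 fold change 5.02, SE 0.5) and Klk6 from 470 to 8280 (3.96, SE 0.49). Connexins of the Gjb group rose in 6 of 6 members: Gjb2 by 2.71 (SE 0.42) and Gjb6 by 2.35 (SE 0.41), with Gjb3, Gjb4 and Gjb5 by 0.36 to 0.41. Camera gave adjusted p = 0.00274 for Klk and 0.0209 for Gjb, and adjusted p = 0.928 with an estimated correlation for both.

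Of 49 Mrpl genes, of the mitochondrial ribosome, 23 rose and none fell, with a median of 0.32, and of 14 Psmd genes, of the proteasome, 11 rose and none fell, with a median of 0.37. Camera gave adjusted p = 8.98e-07 for Mrpl and 0.00274 for Psmd, and adjusted p = 0.928 with an estimated correlation for both. Sodium-coupled transporters of the Slc5a group rose in 5 of 8, among them the glucose transporter Slc5a1 from 1290 to 4180. Of 344 Zfp genes 72 fell and 11 rose, with a median of -0.25. Camera called 15 families up and 2 down, and 0 with an estimated correlation (lowest adjusted p = 0.928).

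Cholesterol synthesis genes rose together, though the camera call of their list was lost with an estimated correlation (adjusted p = 0.416). Fry called the list (adjusted p = 0.00391). Less sterol ligand in KO epidermis could be a cause, which would lower LXR targets. The LXR list had a camera adjusted p of 0.418 in the downward direction, with Abca1 and Mylip down and Smpdl3a up, so the hypothesis could be neither excluded nor upheld.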
